A study of Mus musculus with 19 samples.

How the data were processed

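Messenger RNA of cerebral microvessels was measured in 19 libraries from male C57BL/6 mice, by single-end, strand-specific sequencing of polyadenylated RNA. The labels give 5 groups: room air (titled Room-air, 4 libraries), nicotine-free e-cigarette (Nic-free, 4), e-cigarette with nicotine (Nic, 3), a further room air set (titled air, 4) and cigarette smoke (smoke, 4). Both air sets carry the label of room air exposure. The Room-air set was taken as the control of the e-cigarette groups and the air set as the control of smoke, by the titles alone, since no label links a control to an exposure. The labels give no litter, batch, day or time of collection, and nothing says that equal replicate numbers mark related samples.

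The deposited values are counts, raw reads per Ensembl gene. Per the submitters' processing notes, the authors aligned reads with STAR to the mouse build mm10 and counted them with HTSeq, with versions not stated. Each file lists 39179 genes and 5 summary lines, which name no gene and were kept out of totals and tests. Names were found for 37607 genes and positions are from the GENCODE M21 annotation (GRCm38). Over the 19 libraries 27448 genes had at least 1 count. The strand setting of the counting is not stated, so counts of genes that overlap another gene on the opposite strand are uncertain. The 37 genes of the mitochondrial genome are listed, and the 13 that encode proteins are at 0 in all 19 libraries, so the list of mitochondrially encoded genes was not tested.

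Total counts per library (M, 1e6 reads) were 30.2, 29.8, 25.3 and 26.7 in Room-air 1 to 4, 15.2, 17.5, 19.1 and 15.2 in Nic-free 1 to 4, and 21.8, 26.2 and 28.4 in Nic 1 to 3. They were 13.0, 9.8, 13.5 and 10.6 in air 1 to 4 and 10.5, 7.9, 12.2 and 12.6 in smoke 1 to 4. Intervals from counts cover counting error only, since reads without molecular identifiers are not independent molecules.

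Comparisons were made with edgeR 4.0.16 in R 4.3.3: TMM normalisation, filterByExpr on the groups fitted, estimateDisp, glmQLFit with robust estimation and glmQLFTest, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The 11 libraries of Room-air, Nic-free and Nic shared 1 fit, from which 3 comparisons were taken: each e-cigarette group against Room-air, and Nic against Nic-free. Smoke was compared with air in a fit of those 8 libraries. A fit of all 19 libraries gave the air set against the Room-air set, and the smoke effect minus the nicotine e-cigarette effect. Levels are CPM (counts per 1e6 counts) of the fitted libraries, as mean and SD over libraries, and the error of a log2 fold change is its standard error. These p-values measure only the spread between these samples. The tests were tested on simulated data with 200 changed genes per comparison at the depths and spreads of these libraries. Genes of the lowest levels were not among the changed genes. Counts were drawn independently per gene, so shifts shared by many genes of a library are not covered. The tests recovered 22.4 to 71.6% of genes changed 1.5-fold, 80.6 to 97.0% of those changed 2-fold and 95.5 to 100.0% of those changed 4-fold, and 4.6 to 8.9% of the calls were genes that had not been changed.

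Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, adjusted over the lists with at least 5 genes tested, and beside it with an estimated correlation and with fry, which tests whether the genes of a list move on balance one way. Members past the threshold were counted over all genes tested and adjusted over the list alone. Of all genes tested, 21.8, 3.9, 24.8, 1.6, 22.7 and 5.6% passed, in the order of the comparisons in the report. A list with a share of members near that of its comparison shows no response of its own. The pathway lists were tight and adherens junctions, blood-brain barrier transporters, endothelial Wnt/beta-catenin targets, leukocyte adhesion and endothelial activation, NF-kB and cytokine genes, interferon response, NRF2 and antioxidant genes, aryl hydrocarbon receptor targets, NADPH oxidase and nitric oxide synthases, glucocorticoid-induced genes, circadian clock genes, immediate early genes, hypoxia-induced genes, heat shock and unfolded protein response, basement membrane and matrix, nicotinic acetylcholine receptors, nuclear oxidative phosphorylation and cell cycle genes. The marker lists covered endothelial cells, arterial and venous endothelium, pericytes, smooth muscle, fibroblasts and meninges, astrocytes, microglia, perivascular macrophages, neurons, cortical layer and hippocampal or striatal neurons, oligodendrocytes, oligodendrocyte precursors, choroid plexus and ependyma, erythroid cells, neutrophils and monocytes, and lymphocytes, and ribosomal protein genes were a list for RNA quality. Some genes stand in more than 1 list, such as Slc2a1 and Abcb1a among both transporters and endothelial markers. The mean log2 CPM of each marker list per library was compared between groups with exact permutation tests, two-sided.

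The genes named in the text follow a rule. For each exposure comparison they are the 8 largest changes in each direction among genes past the threshold with a mean CPM of at least 1, the 3 smallest p-values of each called pathway list and of each list with a member past the threshold, and always Ocln, Cldn5, Tjp1, Slc2a1, Mfsd2a, Icam1, Vcam1, Cyp1a1, Cyp1b1, Nqo1 and Hmox1. For the last 2 comparisons they are the 5 largest in each direction. Some genes that the rule names are not reported here. Predicted gene models, pseudogenes and unnamed genes were left out of the largest changes. In the order of the comparisons as listed above, 193, 33, 122, 3, 131 and 13 such genes were left out among the higher and 100, 15, 120, 1, 86 and 32 among the lower. Of the 8 largest changes in the first 4 comparisons they made up 8, 8, 1 and 1 of the higher. Among the lower they made up 0, 1, 4 and 0. Of the 5 largest in the last 2 comparisons they made up 3 and 0 of the higher and 1 and 4 of the lower.

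Groups, tests, lists, this rule and most alternatives were chosen before the data were examined. The alternatives were RLE size factors, no filter on low counts, a filter of 1 CPM, no robust estimation, the replicate number as a block, 1 surrogate variable (sva 3.50.0), the neuron marker list as a covariate, DESeq2 1.42.0, other sets of libraries in the fit, the other air set or both air sets as control, and leaving out each library in turn. Chosen after the data were seen were the removal of GC and transcript length trends (lowess span 0.3), the endothelial and the choroid plexus marker lists as covariates, and leaving out Nic 1 and Nic 2 together. Tables were handled and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.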

Results

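Gene expression was measured in cerebral microvessels, the small vessels of the brain whose endothelial cells form the blood-brain barrier, after exposure of mice to e-cigarette vapour with or without nicotine, to cigarette smoke or to room air. Raw counts were deposited for 19 libraries: 4 of room air (the Room-air set), 4 of nicotine-free e-cigarette, 3 of nicotine e-cigarette, 4 of a further room air set (the air set) and 4 of smoke. Depth, as total counts per library, ran from 25266790 to 30185056 in the Room-air set, 15200536 to 19137859 in the nicotine-free group and 21800157 to 28364198 in the nicotine group. It ran from 9761373 to 13490373 in the air set and 7939180 to 12607538 in the smoke group. Genes with at least 1 count numbered 19326 to 22324 per library. The first principal component held 26.7% of the variance and the next 17.3%. On the first, the Room-air libraries lay at −39.13 to −24.49 and the nicotine libraries at −21.14 to −10.85. The nicotine-free libraries lay at 1.65 to 35.25, the air set at 4.27 to 31.97 and smoke at −29.24 to 30.57. This component thus set the air sets apart from each other.

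Neuronal transcripts were present in every library beside vessel transcripts, at 1.85 to 2.54% of counts for the neuron markers against 0.187 to 0.73% for the endothelial markers. Choroid plexus and ependymal markers, which belong to tissue of the ventricles, ranged from 0.09 to 2.69% of counts and oligodendrocyte markers from 0.963 to 3.25%. Choroid markers were highest in the Room-air set (mean log2 CPM 6.189 ± 0.111, SD, n = 4) and lower in every other group, at 0.313-fold in nicotine-free, 0.406-fold in nicotine and 0.408-fold in the air set. Of 85 exact two-sided permutation tests of 17 lists between groups, none passed after adjustment (lowest adjusted p 0.106), where the smallest p that 4 against 4 libraries allow is 0.0286. To pass after adjustment, most of the 85 tests would have to sit at that floor. The absence of a passing test thus does not show that composition was alike. Reads assigned to no feature in the submitters' counts can still lie within genes, since the feature and strand settings are not stated. They were 30.7 ± 2.28% in the Room-air set and 42.1 ± 2.57% in the nicotine-free group (SD, n = 4 each, exact permutation p 0.0286, adjusted 0.0477). They were 35.4 ± 1.63% in the air set and 30.8 ± 1.85% in the smoke group (exact p 0.0286, adjusted 0.0477). The air set differed from the Room-air set with the same exact and adjusted p. In the nicotine group such reads were 36.4 ± 2.97% (n = 3, exact p 0.0857 against Room-air). Of 88 calls of a gene list by camera over the 6 comparisons, 1 held with an estimated correlation, that of circadian clock genes in smoke against air, and 34 lists passed with fry. The median, mean and test of each called list had the same sign, and they differed in sign in some lists not called, such as hypoxia-induced genes in nicotine against room air (median 0.115, mean 0.028, test lower).

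**Figure D1:**
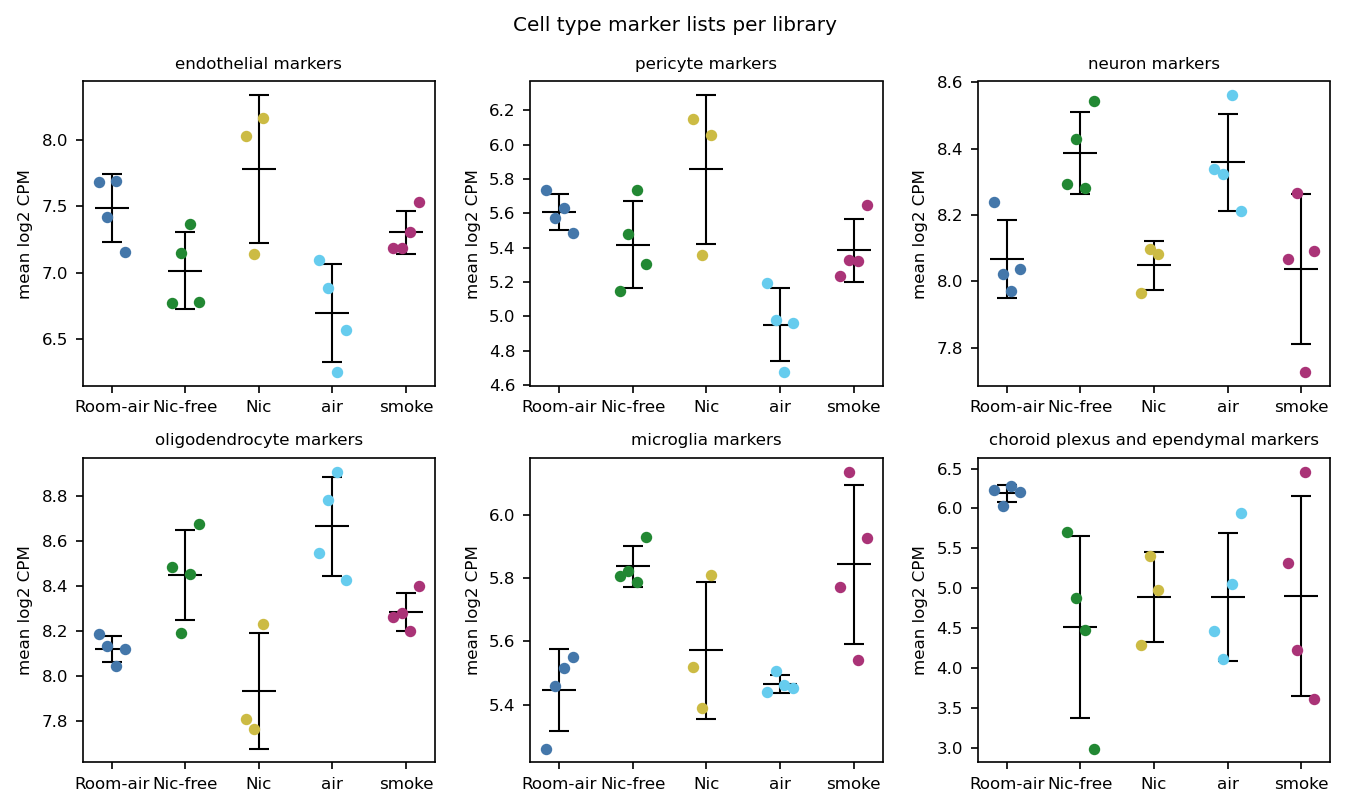
Mean log2 CPM of 6 marker lists in each of the 19 libraries, with group mean and SD as bars. Choroid plexus markers sat highest in the Room-air set (mean 6.189), and endothelial markers lowest in the air set (mean 6.701).

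Nicotine-free e-cigarette against room air asks what the vapour does to the barrier without nicotine. Ocln, which encodes occludin of the tight junctions between endothelial cells, fell to 35.7 ± 4.46 CPM from 68.2 ± 10 in room air (SD, n = 4 each), a log2 fold change of −0.93 ± 0.14 (SE; edgeR adjusted p 0.000921; ENSMUSG00000021638, chromosome 13, 100496507 to 100552718). Slc2a1, the main glucose transporter of the barrier, fell to 375 ± 93 CPM from 807 ± 40.8 (log2 −1.11 ± 0.16, adjusted p 0.000768; ENSMUSG00000028645, chromosome 4, 119108711 to 119137983). Fzd4, a receptor through which Wnt signals maintain the barrier, fell to 6.15 ± 3.1 CPM from 26.5 ± 5.6 (log2 −2.12 ± 0.27, adjusted p 0.000641). Cldn5, the main claudin of brain endothelium (log2 0.13, adjusted p 0.792), Tjp1, a scaffold of tight junctions (−0.24, 0.16), and Mfsd2a, a transporter of lipids with docosahexaenoic acid (−0.37, 0.0932), did not pass. Endothelial markers stood at 0.722-fold of room air per library (exact two-sided permutation p 0.0571).

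Of 18 junction genes 6 fell and none rose (9 and none adjusted over the list alone), among them Ctnnd1 (log2 −0.40) and Ctnna1 (−0.52), catenins of adherens junctions. Among 22 barrier transporters 9 fell and 1 rose (9 and 2 over the list alone), with Slc7a5, a carrier of large neutral amino acids, at −0.72 and Lrp8, a lipoprotein receptor, at −0.46. Of 16 endothelial Wnt targets and receptors 3 fell and none rose (the same over the list alone): Fzd4 and the co-receptors Lrp5 (−0.75) and Lrp6 (−0.69). That share is below the 21.8% of all genes tested that passed, so by count the list shows no response of its own. Basement membrane and matrix genes fell in 11 of 18, with none higher (11 lower and 1 higher over the list alone). They included Lamb1, a laminin chain (−0.74 ± 0.11, adjusted p 0.000969), Timp3, an inhibitor of metalloproteinases (−0.91 ± 0.14, 0.00102), and Col4a1, a collagen of the basement membrane (−0.57). Camera called the lists of junctions (adjusted p 0.000223), transporters (0.0028), Wnt targets (0.029) and matrix (3.59e-06), and their adjusted p were 0.666 to 0.95 with an estimated correlation.

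Glucocorticoid-induced genes had the lowest median of the pathway lists, with a log2 fold change of −0.99, 10 of 17 lower and 1 higher (12 and 3 adjusted over the list alone). Cdkn1a, a cyclin-dependent kinase inhibitor, fell to 23.3 ± 2.52 CPM from 99.8 ± 9.96 (SD, n = 4 each; log2 −2.10 ± 0.10, edgeR adjusted p 6.21e-08; ENSMUSG00000023067, chromosome 17, 29090976 to 29100727). Tsc22d3, the glucocorticoid-induced leucine zipper, fell to 68.2 ± 9.69 CPM from 161 ± 29.4 (log2 −1.24), and Map3k6, a kinase, to 8.43 ± 3.18 from 44.5 ± 11 (log2 −2.39). Of 18 heat shock and unfolded protein response genes 7 fell and none rose (8 and 3 over the list alone). Hspa5, the main chaperone of the endoplasmic reticulum, fell to 382 ± 65.2 CPM from 822 ± 134 (log2 −1.11). Herpud1, which acts in degradation there (−0.69), and Xbp1, a transcription factor of the unfolded protein response (−0.62), fell too. Camera called glucocorticoid-induced genes at an adjusted p of 8.36e-12 and heat shock genes at 0.00042, against adjusted p = 0.521 and 0.7 with an estimated correlation.

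Ribosomal protein genes rose in 23 of 37 with none lower (29 and none adjusted over the list alone), with Rpl38 at a log2 fold change of 0.80, Rps28 at 0.70 and Rps19 at 0.64. Nuclear genes of oxidative phosphorylation rose in 11 of 39 with none lower (11 higher and 1 lower over the list alone), among them Cox6a1 (0.62) and Cox8a (0.54) of cytochrome c oxidase and Ndufb9 of complex I (0.60). Camera called both (adjusted p 6.18e-11 and 0.000739), with adjusted p = 0.7 and 0.95 with an estimated correlation.

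Markers of neurons and glia rose in part. Nrgn, a calmodulin-binding protein of neurons, rose to 1030 ± 130 CPM from 488 ± 30.8 (log2 1.08 ± 0.10, edgeR adjusted p 7.2e-05), and S100b, of astrocytes, to 356 ± 13.3 from 193 ± 18.1 (log2 0.88). Neuron markers rose in 10 of 20 (11 adjusted over the list alone), microglia markers in 9 of 15 (12) and oligodendrocyte markers in 6 of 11 (6), with none lower, and astrocyte markers rose in 7 of 13 with 1 lower (8 and 1). Examples were Rbfox3 (0.76) and Syp (0.64) of neurons, Gfap (0.63) and Sox9 (0.78) of astrocytes, Aif1 (0.96) and C1qb (0.59) of microglia, and Mbp (0.62) of myelin. Markers of cortical layers, hippocampus and striatum rose in 5 of 16 with none lower (8 over the list alone), with Penk, an opioid peptide gene, at 0.66 and Rorb, of cortical layers, at 0.43. Endothelial markers fell in 6 of 20 with none higher (8 over the list alone), such as Adgrl4 (−1.06) and Itm2a (−0.66). Choroid plexus and ependymal markers fell in 2 of 12 (2), Dynlrb2 (−1.36) and Foxj1 (−0.91), with a list median of −1.40. Their share past the threshold was below the 21.8% of all genes tested. Camera called all 7 lists (adjusted p 1.99e-06 for neuron, 5.51e-06 for microglia, 0.00534 for oligodendrocyte, 0.000493 for astrocyte, 0.00256 for cortical, 0.000261 for endothelial and 0.00042 for choroid markers), and their adjusted p were 0.521 to 0.866 with an estimated correlation.

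Other lists were not called as a whole, in a comparison where 21.8% of all genes tested passed. Clock genes changed in both directions, 5 higher and 6 lower of 17 (6 and 6 adjusted over the list alone), with Dbp, a clock output factor, at a log2 fold change of 0.84, Per2, a clock repressor, at −0.56 and Arntl, a clock activator, at −0.32. Dbp passed in 23 of 23 alternatives, at log2 0.71 to 1.22, the only named gene of this comparison to do so. Immediate early genes rose in 6 and fell in 4 of 24 (6 and 5), such as Junb (0.80) and Nr4a2 (0.71) against Maff (−1.59). NF-kB and cytokine genes rose in 4 and fell in 4 of 23 (4 and 4), with Ccl4, a chemokine of low level here, at 1.71 and Nfkb1, a subunit of NF-kB, at −0.38. Of 24 NRF2 and antioxidant genes 3 rose and none fell (3): Gstm1 (0.64) and Gstp1 (0.38), which encode glutathione transferases, and Fth1, ferritin heavy chain (0.60). Among 6 aryl hydrocarbon receptor targets 2 fell (3): Cyp1b1, a cytochrome P450 (−0.81 ± 0.26, adjusted p 0.0421), and Tiparp (−0.39). Hypoxia-induced genes changed in 3 of 15, with Hk2, a hexokinase, higher (0.50) and Vegfa, an endothelial growth factor, lower (−0.32); over the list alone 1 was higher and 3 lower. Single members passed among interferon response (Irf9, −0.44), NADPH oxidase and nitric oxide synthase (Rac2, 0.74), nicotinic receptor (Chrnb4, −1.80), arterial and venous (Efnb2, 0.32), pericyte (Abcc9, −0.48), fibroblast (Pdgfra, −0.33), perivascular macrophage (Cd163, −0.71), erythroid (Bpgm, 0.43) and lymphocyte (Ighm, 0.55) genes. Oligodendrocyte precursors had 1 gene higher, Cspg5 (0.38), and 1 lower (2 and 2 over the list alone). No leukocyte adhesion gene of 11, no cell cycle gene of 18, and no smooth muscle or neutrophil marker passed. Icam1 and Vcam1, adhesion molecules for leukocytes, had log2 fold changes of −0.11 (adjusted p 0.892) and −0.66 (0.139), and the antioxidant genes Nqo1 and Hmox1 of −0.71 (0.136) and 0.02 (0.966). Cyp1a1, the classical smoke-induced cytochrome P450, was at most 0.156 CPM in any library and was tested in no comparison.

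Across 17235 genes tested with edgeR, 1954 rose and 1799 fell. The 8 largest rises were all predicted gene models, pseudogenes or unnamed genes, which the naming rule leaves out. Next by that rule were rises that included Mir99a (log2 1.94 ± 0.36), a microRNA gene, and Mir99ahg (1.35). Caln1, a calcium-binding protein of neurons (1.39 ± 0.11), and Ido1, which degrades tryptophan (1.31 ± 0.19), were also among them. The largest falls by the rule included Prrg4 (−3.11 ± 0.52), Best3 (−2.43), Irx2 (−2.21) and Angptl4, an inhibitor of lipoprotein lipase (−2.04). With the air set as control in place of the Room-air set, 699 genes passed, and Ocln (log2 0.21, adjusted p 0.592), Slc2a1 (0.42, 0.413), Cdkn1a (0.04) and 17 other named genes changed sign, while 3 of the 15 lists kept their camera call and 6 were called the other way (transporters, Wnt targets, ribosomal protein, oxidative phosphorylation, endothelial and oligodendrocyte genes). Ocln and Slc2a1 passed in 19 of 23 alternatives each, with adjusted p from 8.07e-08 to 0.592 and 2.1e-09 to 0.413, and with neuron or choroid markers as a covariate 8 or 121 genes passed, where the median fold change of called genes was 0.85 or 0.91 times as large and the median SE 1.83 or 1.54 times.

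**Figure D2:**
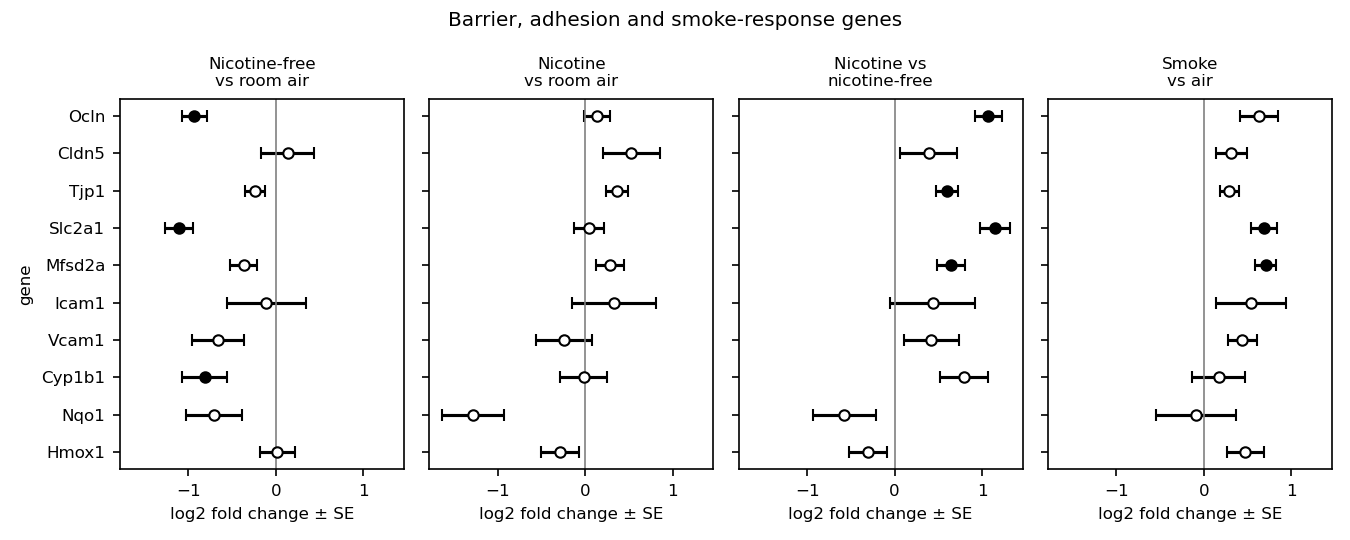
Log2 fold changes with SE of 10 genes of the barrier, leukocyte adhesion and smoke response, in 4 comparisons, with filled points for adjusted p under 0.05 (edgeR). Ocln stood at −0.93 in nicotine-free against room air and at 1.07 in nicotine against nicotine-free.

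Nicotine e-cigarette against room air asks what the vapour does with nicotine in it. Atp5g1, which encodes subunit c of ATP synthase, fell to 36.5 ± 4.37 CPM (SD, n = 3) from 67.7 ± 4.28 (n = 4), a log2 fold change of −0.89 ± 0.12 (SE; edgeR adjusted p 0.0152; ENSMUSG00000006057, chromosome 11, 96068852 to 96075670). Ndufa1, of complex I, fell to 27.1 ± 8.32 CPM from 52.5 ± 5.41 (log2 −0.95 ± 0.16, adjusted p 0.0197), and so did Atp5a1, another ATP synthase subunit (−0.61, 0.0197). Tfrc, the transferrin receptor, rose to 251 ± 72.6 CPM from 155 ± 5.88 (log2 0.69 ± 0.14, adjusted p 0.0257), and Slc40a1, the iron exporter, by 0.77 ± 0.16 (0.0249). Ocln (log2 0.14, adjusted p 0.612), Cldn5 (0.53, 0.353), Tjp1 (0.36, 0.101), Slc2a1 (0.04, 0.915) and Mfsd2a (0.28, 0.297) did not pass, while all 5 rose with the air set as control (such as Ocln at 1.27 and Slc2a1 at 1.56).

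Nuclear oxidative phosphorylation genes fell in 21 of 39 with none higher (36 adjusted over the list alone), with a median log2 fold change of −0.49 (camera adjusted p 5.76e-31), and adjusted p = 0.671 with an estimated correlation. Of 24 NRF2 and antioxidant genes 2 fell and none rose (5 over the list alone): Gpx4, a peroxidase that protects membrane lipids (−0.52), and Sod1, superoxide dismutase (−0.46). Glucocorticoid-induced genes fell in 2 of 17 (8), the metallothioneins Mt1 (−0.57) and Mt2 (−0.53). Barrier transporters rose in 4 of 22 with none lower (7 higher and 1 lower over the list alone), among them Slc16a1, a carrier of lactate and ketone bodies, at 117 ± 41.1 CPM against 66.4 ± 3.67 (log2 0.82 ± 0.16). Immediate early genes rose in 2 of 24 (3), Klf6 (0.54) and Nr4a1 (0.51). Camera also called the ribosomal protein genes (lower, adjusted p 7.44e-08), interferon response genes (higher, 0.0076), endothelial markers (higher, 0.00335) and choroid markers (lower, 0.00335), in none of which a gene passed, with 2 choroid markers lower over the list alone. Pericyte markers (0.0115, Abcc9 at 0.59) and microglia markers (0.0454, Gpr34 at 0.53) were called higher with 1 member each past the threshold (2 each over the list alone). Camera adjusted p were 0.000666 for NRF2, 1.91e-05 for glucocorticoid, 0.00091 for transporter and 0.000142 for immediate early genes, and adjusted p = 0.935 with an estimated correlation for all 10 lists other than oxidative phosphorylation. Per library, endothelial markers stood at 1.23-fold of room air (exact two-sided permutation p 0.429) and neuron markers at 0.986-fold (0.886), where 3 against 4 libraries were compared.

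Lists not called held few changes. The glycolytic enzymes Pgk1 (−0.74) and Aldoa (−0.46) fell among hypoxia-induced genes, Mmp2, a matrix metalloproteinase, fell (−0.69; 2 matrix genes over the list alone), and Arntl rose (0.30). Ppp1r1b, a phosphoprotein of dopamine-receptive neurons, fell by more (−0.89 ± 0.15, edgeR adjusted p 0.0197). Aldh1l1 of astrocytes fell (−0.50; 2 over the list alone), and Efnb2 of arteries (0.43) and Slc4a1 of red cells (1.21) rose. No junction gene of 18, no leukocyte adhesion gene and no Wnt target passed (for Wnt targets 2 higher and 1 lower adjusted over the list alone), and Icam1 (0.33, 0.723), Vcam1 (−0.24, 0.69), Cyp1b1 (−0.02, 0.978), Nqo1 (−1.28 ± 0.35, 0.0639) and Hmox1 (−0.29, 0.435) did not pass.

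Of 17235 genes tested, 210 rose and 460 fell, a balance that turned with endothelial markers as a covariate (1451 and 1119) and without Nic 3 (1621 and 1335). The 8 largest rises were all predicted gene models, pseudogenes or unnamed genes, and the largest of the others was that of Fam71d (log2 1.05). By the naming rule the 8 largest falls ran from Smim22 (−3.65 ± 0.65) and Cndp1, a carnosinase (−2.05), to Marveld3, of tight junctions (−1.84). Fewer passed without single libraries: 0 genes without Room-air 2 (3581 with unadjusted p under 0.05) or without Nic 1 (2424), 111, 358 and 324 without Room-air 1, 3 and 4, and 422 without Nic 2, against 2956 without Nic 3, where 4 of the 11 lists kept their camera call. With choroid markers as a covariate, a setting chosen after the data were seen, 0 genes passed (2090 unadjusted; fold changes of called genes 0.84 and SE 1.32 times as large), with endothelial markers 2570, with DESeq2 1629, and with 1 surrogate variable 1037. The count was 348 with all 19 libraries in 1 fit, 4961 with the air set as control, 1080 with both air sets and 3 without Nic 1 and Nic 2 together.

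**Figure D3:**
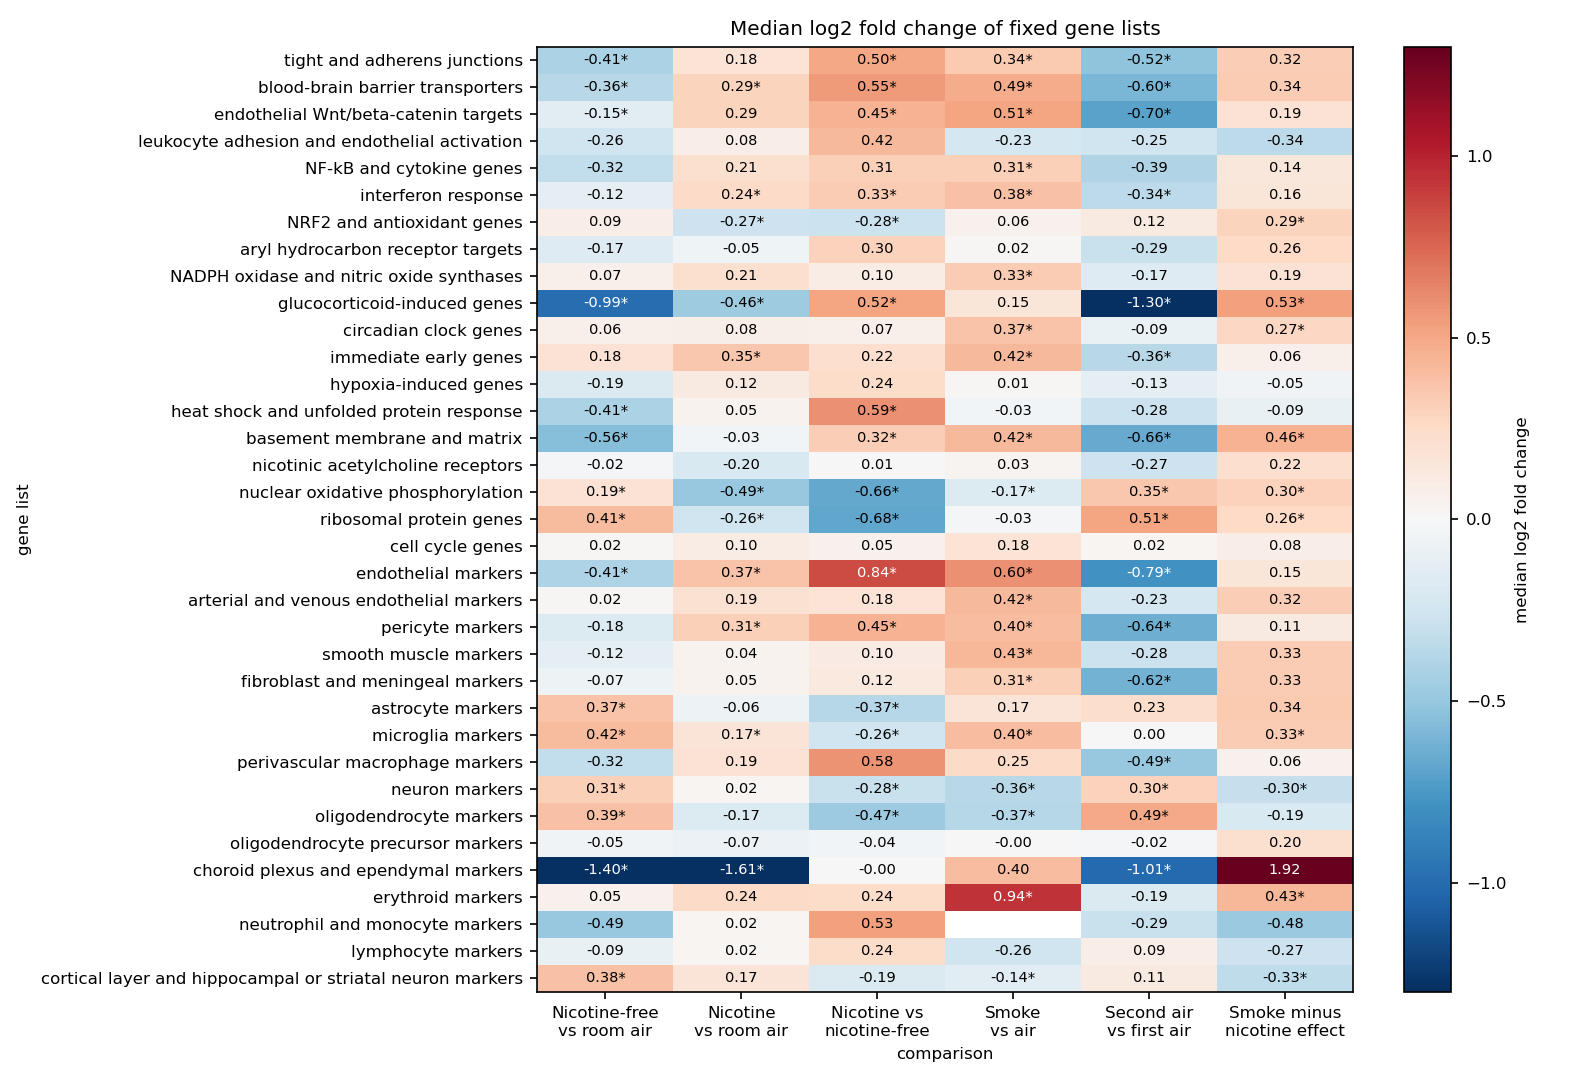
Median log2 fold change of the members of each gene list in the 6 comparisons, with stars for a camera adjusted p under 0.05. Oxidative phosphorylation stood at −0.49 in nicotine against room air and clock genes at 0.37 in smoke against air.

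Nicotine against nicotine-free e-cigarette asks what nicotine itself adds. Ocln was higher with nicotine, at 75 ± 15.4 CPM (SD, n = 3) against 35.7 ± 4.46 (n = 4), a log2 fold change of 1.07 ± 0.15 (SE; edgeR adjusted p 0.000423), and Slc2a1 was at 830 ± 153 CPM against 375 ± 93 (log2 1.15 ± 0.17, 0.000617). Tjp1 (0.60, 0.00378) and Mfsd2a (0.65, 0.00987) also passed, and Cldn5 (0.39, 0.415) did not. Cdkn1a stood at 78.9 ± 5.87 CPM against 23.3 ± 2.52 (log2 1.76 ± 0.11, adjusted p 1.34e-06). Endothelial markers per library were at 1.7-fold of the nicotine-free group (exact two-sided permutation p 0.143, with 3 against 4 libraries) and neuron markers at 0.791-fold (0.0286).

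Vessel lists were higher with nicotine, with no member lower: junction genes in 7 of 18 (9 adjusted over the list alone), barrier transporters in 13 of 22 (15), Wnt targets in 9 of 16 (10), matrix genes in 6 of 18 (6), endothelial markers in 12 of 20 (17) and pericyte markers in 5 of 12 (5). Examples were Abcg2, an efflux pump (log2 0.99), Fzd4 (1.28), Tcf7, a transcription factor of Wnt signalling (0.72), Col4a1 (0.76), Lamc1, a laminin chain (0.82), Adgrl4 (1.58) and Rgs5, of pericytes (0.91). Heat shock genes were higher in 10 of 18 (10), with Hspb1, a small heat shock protein, at 1.99 and Hspa5 at 1.01, and interferon response genes in 8 of 29 (9), with Irf9 at 0.83 and Usp18 at 0.90. The interferon share was near the 24.8% of all genes tested that passed. Glucocorticoid-induced genes were higher in 5 and lower in 2 of 17 (7 and 2), with Tsc22d3 at 1.03 and Mt1 at −1.14. Camera adjusted p were 4.41e-05 for junctions, 1.42e-07 for transporters, 0.000304 for Wnt targets, 0.000671 for matrix, 1.65e-08 for endothelial and 0.00171 for pericyte genes. They were 0.000844 for heat shock, 0.00349 for interferon and 0.0023 for glucocorticoid genes. For these lists the adjusted p were 0.601 to 0.843 with an estimated correlation.

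Oxidative phosphorylation genes were lower in 36 of 39 (37 adjusted over the list alone), with a median of −0.66, and ribosomal protein genes in 33 of 37 (35), with none higher in either. Ndufb9 stood at a log2 fold change of −0.95 ± 0.11 (edgeR adjusted p 0.000236), Uqcr11, of complex III, at −0.99, Cox6a1 at −1.01 and Rps19 at −0.80. NRF2 and antioxidant genes were lower in 8 of 24 (8), with Fth1 at −1, Gstm1 at −0.93 and Sod1 at −0.69. Markers of neurons were lower in 7 of 20 (8), of astrocytes in 9 of 13 (9), of oligodendrocytes in 7 of 11 (7) and of microglia in 4 of 15 (6), with none higher, such as Nrgn (−1.17 ± 0.11), S100b (−1.03), Mbp (−1.01) and Aif1 (−0.79). The microglia share was near the 24.8% of all genes tested that passed. Camera adjusted p were 4.42e-30, 1.52e-23, 0.00107, 6.63e-05, 5.04e-05, 0.000304 and 0.0179 for these 7 lists in turn, and adjusted p were 0.553 to 0.805 with an estimated correlation.

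Lists not called held changes of both signs. Clock genes were higher in 6 and lower in 3 of 17 (6 and 5 adjusted over the list alone), with Per2 at log2 0.87, Arntl at 0.62 and Dbp at −0.73, and immediate early genes in 7 and 2 of 24 (8 and 3), with Klf2, a flow-induced factor, at 1.00. NF-kB and cytokine genes were higher in 4 of 23, with Nfkb1 at 0.52, Nos2, the inducible nitric oxide synthase, at 1.18 and Tlr4, the endotoxin receptor, at 1.06. Hypoxia-induced genes were higher in 4, such as P4ha1 (0.68), and lower in 3, such as Aldoa (−0.69), and oligodendrocyte precursor markers had 1 higher and 3 lower, with Olig1 at −0.54. Single members passed among aryl hydrocarbon receptor targets (Aldh3a1, −1.19) and arterial and venous (Ephb4, 0.81), smooth muscle (Smtn, 0.68), fibroblast (Lum, 0.56), perivascular macrophage (Mrc1, 0.72), erythroid (Bpgm, −0.63), neutrophil and monocyte (Csf3r, 0.45) and lymphocyte (Ighm, −0.53) markers. Among cell cycle genes 2 passed, Birc5 (0.67) and Ccnb2 (0.61), and none over the list alone. Icam1 (0.44, 0.554), Vcam1 (0.42, 0.372), Cyp1b1 (0.80, 0.0532), Nqo1 (−0.57, 0.27) and Hmox1 (−0.31, 0.334) did not pass in this comparison.

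In all, 2131 genes were higher and 2142 lower of 17235 tested. The 8 largest differences by the naming rule ran from Slfn3 (log2 2.21) to Plaur, the urokinase receptor (1.89), and among lower genes included Pgam2, a glycolytic enzyme (−1.59), Fgf4 (−1.56) and Mt3, a metallothionein of the brain (−1.29). With neuron markers as a covariate 7 genes passed and neither Ocln (log2 0.73, adjusted p 0.173) nor Slc2a1 (0.78, 0.206) did, as the median SE grew 1.73 times, though both passed in the other 20 of 21 alternatives. No air set enters this comparison, so these alternatives hold no change of control. The nicotine-free group shared many of its changes with the unexposed air set, and depth was 15.2 to 19.1 M against 21.8 to 28.4 M with nicotine. A difference between library sets other than nicotine cannot be told apart here. Without Nic 1 2401 genes passed, without Nic 1 and Nic 2 together 1511, and with endothelial markers as a covariate, chosen after the data were seen, Cldn5 was lower with nicotine (log2 −0.72, adjusted p 0.0122).

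Smoke against air asks what cigarette smoke does to the same vessels. Dbp, an output factor of the circadian clock, rose to 168 ± 21.5 CPM from 80.4 ± 9.84 (SD, n = 4 each), a log2 fold change of 1.06 ± 0.12 (SE; edgeR adjusted p 0.00779; ENSMUSG00000059824, chromosome 7, 45705088 to 45710203). Per1, a clock repressor, rose to 135 ± 5.1 CPM from 70.3 ± 12.6 (log2 0.94 ± 0.11, adjusted p 0.0101; ENSMUSG00000020893, chromosome 11, 69095217 to 69109960), and Ciart, another repressor, to 22 ± 5.38 from 10.4 ± 0.961 (log2 1.08 ± 0.16, 0.0241). Of 17 clock genes 7 rose and 1 fell (12 and 3 adjusted over the list alone; camera adjusted p 2.01e-09, fry 0.000179), with a median log2 fold change of 0.37, and adjusted p = 0.0165 with an estimated correlation. Chosen after its values were seen, Arntl, the clock activator, was the member that fell, to 37.2 ± 1.05 CPM from 53.3 ± 5.61 (log2 −0.52 ± 0.09, adjusted p 0.0386). Also chosen after their values were seen, Per2 (0.78 ± 0.13, 0.0303) and Nr1d1, a nuclear receptor of the clock (0.69, 0.0386), rose. The list was called in 21 of 21 other settings, and Dbp passed in 20 of 22, but not without smoke 1 (log2 1.06) or with the endothelial covariate (log2 1.14), with adjusted p from 2.33e-11 to 0.409 over the 22. Per1 passed in 15 of 22 and stood at −0.11 with the Room-air set as control, and Ciart passed in 16 of 22.

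**Figure D4:**
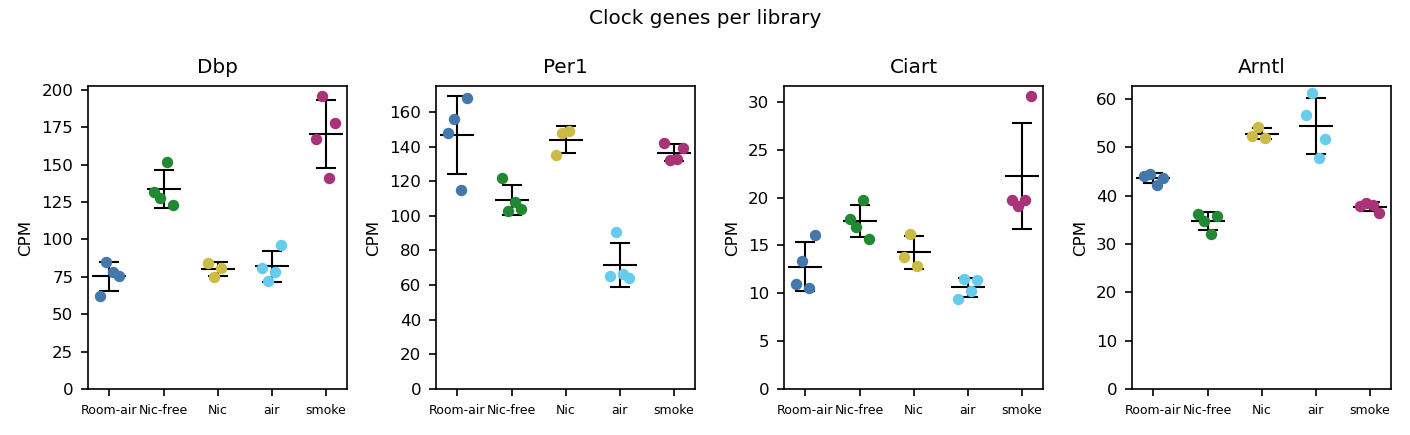
CPM of 4 clock genes in each of the 19 libraries, with group mean and SD as bars. Dbp averaged 170 CPM in smoke and 82 in the air set, and Arntl 37.7 and 54.4.

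Barrier transporters rose in 9 of 22 with none lower (14 adjusted over the list alone). Slc7a5 rose to 150 ± 24.4 CPM from 78.3 ± 9.68 (SD, n = 4 each; log2 0.94 ± 0.13, edgeR adjusted p 0.0164), Mfsd2a to 60.6 ± 9.1 from 37.1 ± 3.7 (log2 0.71 ± 0.12, 0.0309), and Slc2a1 to 437 ± 54.4 from 271 ± 53.5 (log2 0.69 ± 0.15, 0.0457). Of 18 junction genes 1 rose (11 over the list alone), Jam2, a junctional adhesion molecule (0.62), and Ocln (0.62, 0.156), Cldn5 (0.31, 0.375) and Tjp1 (0.29, 0.158) did not pass. Endothelial markers rose in 3 of 20 (17), with Itm2a at 1.14 and Abcb1a, the efflux pump P-glycoprotein, at 0.78, and Wnt targets in 2 of 16 (11), Lrp5 (0.80) and Tnfrsf19 (0.45). Matrix genes rose in 3 of 17 (6), Lamb2 (0.67), Timp3 (0.59) and Hspg2, perlecan (0.61), and 1 pericyte marker of 12 rose (10), Notch3 (0.76). Endothelial markers per library were at 1.52-fold of air (exact two-sided permutation p 0.0286) and neuron markers at 0.801-fold (0.0571). Camera adjusted p were 1.06e-14 for transporters, 2.84e-07 for junctions, 2.85e-16 for endothelial markers, 1.13e-10 for Wnt targets, 2.96e-06 for matrix and 9.33e-08 for pericytes, and adjusted p = 0.267 with an estimated correlation for each.

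Immediate early genes rose in 3 of 24 (7 adjusted over the list alone), among them Klf4, a transcription factor of endothelium (log2 0.97 ± 0.16), and Maff (1.03). NF-kB and cytokine genes rose in 1 of 15 (3), Nfkbia, an inhibitor of NF-kB (0.68). Microglia markers rose in 1 of 15 (12), Csf1r, the receptor that maintains microglia (0.71), and erythroid markers in 2 of 6 (5), Alas2 of heme synthesis (1.26) and Hbb-bt, a beta globin (0.82). Neuron markers fell in 1 of 20 (10), Snap25 of synaptic vesicle release (−0.74), and oligodendrocyte markers in 1 of 11 (8), Ugt8a of myelin lipid synthesis (−0.51). Smooth muscle markers rose in 1 of 10 (1), Smtn (0.65). No member passed of the interferon response (8 higher over the list alone), NADPH oxidase and nitric oxide synthase (2), arterial and venous (2), fibroblast (1), oxidative phosphorylation and cortical or striatal lists (2 lower over the list alone in the last). Of the interferon genes, Ifit3b was at 0.88 (adjusted p 0.0611) and Irf9 at 0.54 (0.062). Camera called these lists too. The adjusted p were 2.21e-06 for immediate early genes, 0.0375 for NF-kB, 2.45e-09 for microglia, 4.38e-07 each for erythroid and neuron and 8.62e-08 for oligodendrocyte genes. They were 0.000144 for smooth muscle, 9.33e-08 for interferon, 0.00424 for NADPH oxidase, 6.23e-05 for arterial, 0.00236 for fibroblast, 3.68e-05 for oxidative phosphorylation (lower) and 0.01 for cortical markers (lower). For these 13 lists the adjusted p were 0.267 to 0.597 with an estimated correlation.

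Not called were glucocorticoid-induced genes (none past the threshold, 2 higher adjusted over the list alone), heat shock genes (Asns, asparagine synthetase, lower at −0.46; 2 over the list alone), and NRF2, aryl hydrocarbon receptor, leukocyte adhesion, ribosomal and choroid genes, of which none passed. Icam1 (log2 0.54, 0.513), Vcam1 (0.44, 0.172), Cyp1b1 (0.17, 0.804), Nqo1 (−0.09, 0.938) and Hmox1 (0.47, 0.245) did not pass.

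Gh, which encodes growth hormone of the pituitary, was the largest rise, at 4.99 ± 1.43 CPM against 0.0563 ± 0.0718 (SD, n = 4 each; log2 6.06 ± 0.49, edgeR adjusted p 0.000481; ENSMUSG00000020713, chromosome 11, 106300271 to 106301865). Its 210 reads against 3 give a ratio of 75.9 with a 95% counting interval of 25.6 to 371. It was followed by Fmo2, a flavin monooxygenase (1.82 ± 0.25), Atf3, a stress-induced transcription factor (1.44), and Inmt, a methyltransferase (1.29), and among falls by Vsnl1 (−1) and Pcp4 (−0.98), both calcium-signalling genes of neurons. Of 15232 genes tested, 165 rose and 79 fell. Without single libraries 1 gene passed (without smoke 1), 5, 3 and 17 (air 2, 3 and 4), 62, 133 and 11 (smoke 2, 3 and 4) or 192 (air 1), and with endothelial markers as a covariate, chosen after the data were seen, 0 did (1240 unadjusted; fold changes of called genes 0.88 and SE 1.63 times as large). Passing genes numbered 5 with replicate number as a block, 42 without GC and length trends, 53 with both air sets as control and 904 with DESeq2, and with the Room-air set as control 1027 passed, while Slc2a1 (−0.86), Slc7a5 (−0.58) and 15 other named genes that had passed changed sign, as did Ocln (−0.54), Cyp1b1 (−0.81) and 3 more that had not, and 3 of the 20 lists kept their camera call, 11 changed direction and 3 were called the other way.

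The air set against the Room-air set asks whether the groups under the same label of room air differ. Map3k6 stood at 7.86 ± 2.44 CPM in the air set and 44.3 ± 11.2 in the Room-air set (SD, n = 4 each; log2 −2.51 ± 0.26, edgeR adjusted p 2.03e-05). Fzd4 was at 4.73 ± 1.25 against 26.4 ± 5.73 (−2.48 ± 0.36, 0.000356). The 5 largest falls also held Best3 (−2.72), Prrg4 (−2.37) and Plin4, a lipid droplet protein (−2.16). Among the genes higher in the air set were Krt7, a keratin (1.70), Myh3, a myosin (1.51), Ndufb4 (1.45) and Rpl39 (1.44). Of 16557 genes tested, 1777 were higher and 1984 lower in the air set.

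Lower in the air set were glucocorticoid-induced genes, 12 of 17 (14 adjusted over the list alone, with 1 higher), barrier transporters, 15 of 22 (18), endothelial markers, 13 of 20 (16). Also lower were matrix genes, 11 (11), junction genes, 11 (12), Wnt targets, 8 (14), pericyte markers, 8 (10), fibroblast markers, 7 (8), interferon genes, 4 (3), and perivascular macrophage and choroid markers, 2 and 1 (2 and 1). The interferon and choroid shares were below the 22.7% of all genes tested that passed. Immediate early genes were lower in 8 and higher in 1 (9 and 1). Higher in the air set were ribosomal protein genes, 25 of 37 (29), oxidative phosphorylation genes, 18 of 39 (23), and neuron and oligodendrocyte markers, 6 each (6 and 8). Camera called these 16 lists, at adjusted p from 5.35e-17 for glucocorticoid-induced genes to 0.014 for perivascular macrophage markers, and adjusted p were 0.0514 to 0.707 with an estimated correlation. Endothelial markers per library were at 0.58-fold of the Room-air set (exact two-sided permutation p 0.0286) and neuron markers at 1.22-fold (0.0571). The call count fell to 1230 with neuron and 765 with endothelial markers as a covariate, and no library's omission brought it under 2415.

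Fold changes of nicotine-free against room air and of the air set against the Room-air set, which share a control, correlated across 16535 genes at r 0.725, where genes are not independent replicates. Simulated comparisons that share only a control gave r 0.454, and with separate pairs of Room-air libraries as control r was 0.474 to 0.564. In both comparisons 868 genes rose and 973 fell, against 204 and 212.7 if independent, which a shared control does not make them, and 11 moved in opposite directions. With separate pairs of controls 132 to 229 rose and 275 to 449 fell in both, against 21.3 to 78.1 and 32.4 to 103.4 if independent. Each comparison then has fewer control libraries, so fewer genes can pass and the counts are not on an equal footing. The covariance was 0.141 with the shared control and 0.111 to 0.126 with separate pairs. For nicotine-free and nicotine against room air r was 0.462 (0.447 simulated, and 0.14 to 0.308 with separate pairs). The covariance of these fold changes was 0.0806, against 0.0218 simulated and a mean of 0.0467 with separate pairs. In both, 66 genes rose and 154 fell, against 0 and 0 simulated, and 41 moved in opposite directions. With separate pairs 0 to 47 rose and 0 to 2 fell in both. The like values of r thus do not show that only the control was shared. For nicotine against room air and smoke against air r was −0.168, and for nicotine-free against room air and smoke against air −0.384.

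**Figure D5:**
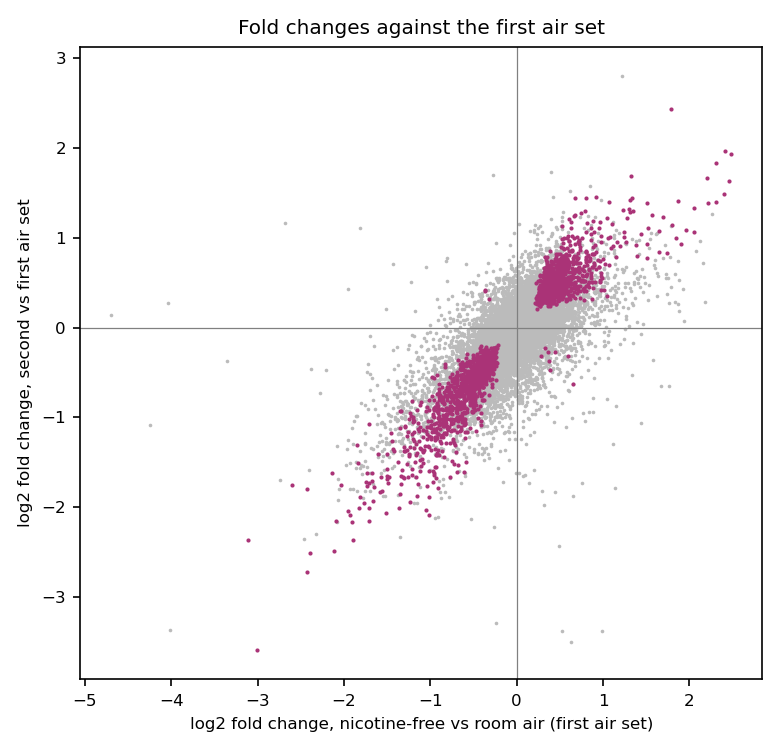
Log2 fold change of each gene in the air set against the Room-air set (the second and first air set on the axes), plotted over that in nicotine-free against the same Room-air set. Coloured points passed in both (868 higher and 973 lower in both, against 132 to 229 and 275 to 449 with separate pairs of controls). Separate pairs leave fewer control libraries per comparison, so fewer genes can pass.

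Smoke effect minus nicotine e-cigarette effect asks which genes respond to smoke differently from nicotine vapour, each against its own air set. Dbp (difference in log2 fold change 0.97 ± 0.17, SE, edgeR adjusted p 0.0106), Per1 (0.96 ± 0.17, 0.0114), Ciart (0.92 ± 0.23, 0.0315) and, with the opposite sign, Arntl (−0.80 ± 0.11, 0.00337) differed. Barrier genes with a larger smoke effect were Fzd4 (2.40 ± 0.51, 0.0233), Lrp5 (1.09 ± 0.25, 0.0243) and Slc7a5 (0.85 ± 0.22, 0.0345). These differences include the gap between the air sets, which was −2.48 for Fzd4, −1.48 for Lrp5 and −1.51 for Slc7a5, and against the Room-air set the smoke effect was −0.69 for Lrp5, −0.58 for Slc7a5 and −0.11 for Per1, where the nicotine effect on Per1 was −0.03. The largest differences by the naming rule were Best3 (3.76 ± 0.97), Acss3 (2.65), Sntb1 (2.58), Ccdc187 (2.49) and Fzd4 in 1 direction, and Pou2f3 (−2.13), Samd15 (−1.34), Nkapl (−1.25), Lemd1 (−1.22) and Lrch2 (−1.13) in the other. Of 16557 genes tested, 461 had a larger and 464 a smaller smoke effect, clock genes among them in 5 and 1 of 17 (8 and 2 adjusted over the list alone; camera adjusted p 0.0263), with adjusted p = 0.427 with an estimated correlation. Camera also called glucocorticoid-induced genes (3 larger, 5 over the list alone; 0.00255), oxidative phosphorylation (2, 2; 4.06e-05), matrix (1; 0.0129), microglia (1; 0.0321), NRF2 (none; 0.00601), ribosomal protein (none; 0.0321) and erythroid genes (none; 0.0352) as larger. The shares of oxidative phosphorylation and matrix members past the threshold were near the 5.6% of all genes tested. Called as smaller were neuron markers (4, 5 over the list alone; 0.00255) and cortical or striatal markers (3, with 1 larger and 5 smaller over the list alone; 0.0316), and for these 9 lists adjusted p = 0.9 with an estimated correlation. Without single libraries 13 (Nic 1), 53 (Nic 2), 460 and 238 (Room-air 1 and 2), 207, 383 and 588 (air 1, 2 and 3), 469 (smoke 2) or 2476 genes (Nic 3) passed, and 0 (1583 unadjusted) without Nic 1 and Nic 2 together.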

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

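The tests of explanations here were chosen after the results were seen, and so was the count of splits for the clock list, while the other counts of splits of the samples were planned before.

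Fold changes were shared between the nicotine-free group and the air set, an unexposed group, both against the Room-air set, so exposure to vapour cannot be their only source. Reads assigned to no feature were also more frequent in both, at 42.1% and 35.4% against 30.7% in the Room-air set. Ribosomal protein genes, the list for RNA quality, were called higher in both, and RNA quality as a source was not tested. Noise of the shared control is excluded as the whole cause, since with separate pairs of Room-air libraries the covariance of the fold changes was at least 0.111, against 0.0217 in simulation. A lower share of endothelial RNA would by itself raise the other cell types alike. Of 10 pairs of other cell types, 4 in the air set and 3 in the nicotine-free group moved apart without overlap between libraries. Chance gives 2.86% per pair of 4 against 4. All 4 in the air set involve the oligodendrocyte list and all 3 in the nicotine-free group the oligodendrocyte precursor list, so a change in these cells stays open. The other pairs overlapped, and the list set apart was not the same in the air set and the nicotine-free group. A lower share of endothelial RNA is thus not excluded as the source of the shared changes. A difference between library sets other than exposure cannot be told apart from the groups, because no label gives a batch, and 313 of 3680 nicotine-free calls were kept against the air set while 1243 changed sign.

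Oxidative phosphorylation transcripts were lower in the nicotine libraries (median log2 fold change −0.49 with a gene SE of 0.12). GC content and transcript length are excluded as the whole cause, since the median was −0.46 with that trend removed and 22 members passed, and so is a different share of neuronal RNA, since neuron markers differed by −0.021. With choroid plexus markers as a covariate the median was −0.43, but the 21 calls fell to 0 as the gene SE went from 0.12 to 0.15. As 80.4% of the covariate's variance lay between the groups, this fit cannot exclude choroid RNA as the cause. The median was −0.46, −0.39 and −0.61 without Nic 1, Nic 2 or Nic 3, with 0, 9 and 34 members past the threshold in turn. Without Nic 1 and Nic 2 together it was −0.27, in a fit that leaves 1 nicotine library assumed to vary like the other groups. Ribosomal protein genes, the list for RNA quality, were called lower here too. Both lists were called higher in the nicotine-free group and in the unexposed air set, while in smoke against air only oxidative phosphorylation was called. RNA quality and a difference between library sets were not tested for this list. An effect of nicotine vapour stays open beside them, in a comparison with 3 exposed libraries.

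Clock genes were higher in the smoke libraries, with a median log2 fold change of 0.37. The median was 0.44 with endothelial markers as a covariate, where the 8 calls fell to 0 as the gene SE went from 0.11 to 0.19. The median thus did not shrink, but 60.8% of the covariate's variance lay between the groups. The fit cannot separate the 2 well, so a higher share of endothelial RNA is not excluded. GC content and transcript length are excluded as the whole cause, with a median of 0.34 after the trend was removed and 4 members past the threshold. A different time of collection cannot be told apart from smoke, since Arntl moved against Dbp and Per1 (−0.52), as it would along the day, and no collection times are given. Both this and an effect of smoke on the clock of the vessels may hold.

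For the number of genes called, only the real split reached its own count in each comparison. That is 1 of 35 splits of the libraries, or 1 of 100 for the smoke effect minus the nicotine effect. With 35 splits this is the smallest share possible. Each split was fitted anew, and mixed splits put unlike libraries into 1 group, which can widen the fitted spread. Chance is thus unlikely as the source of these counts, but not excluded. The real counts of 3753, 670, 4273, 244, 3761 and 925, in the order of the report, stood against highest other counts of 1, 15, 163, 0, 11 and 500. Chance cannot be excluded for the number of gene lists called by camera at the preset correlation: 15 lists against a highest other of 22 for nicotine-free against room air (16 of 35 splits as large), 11 against 26 for nicotine against room air (26 of 35), 16 against 23 for nicotine against nicotine-free (23 of 35), 20 against 24 for smoke against air (7 of 35), 16 against 24 for the air sets (12 of 35) and 10 against 25 for smoke minus nicotine (67 of 100). Why other splits called more lists was not tested. The clock list in smoke against air had a −log10 camera p of 9.63 against 3.4 in the highest other split (1 of 35 as large), but the list was singled out after its result was seen, and the count makes no allowance for that choice.

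The smoke effect differed from the nicotine effect, by a test of the difference itself in edgeR, in 925 genes, of which 32 are named in the text. Each effect is against its own air set, the air sets differed in 3761 genes, and no alternative with a common control was run, so these differences may lie in the controls in part or whole. With the Room-air set as control the smoke effect took the opposite sign for Lrp5 (−0.69), Slc7a5 (−0.58), Timp3 (−0.60), Nfkbia (−0.82), Per1 (−0.11), Snap25 (0.03) and Dpysl2 (0.17), and for Fzd4 the gap between the air sets (−2.48) is as large as the difference. Among genes whose smoke effect kept its sign in every alternative were Dbp (at least 0.97), Ciart (0.81), Nr1d1 (0.41), Csf1r (0.47) and Arntl (at most −0.21). Their difference from the nicotine effect was not tested against a common control. The difference in log2 fold change was −0.80 for Arntl, 0.97 for Dbp, 0.96 for Per1, 0.92 for Ciart and 0.68 for Nr1d1 among clock genes, 1.09 for Lrp5, 2.40 for Fzd4, 0.85 for Slc7a5 and 0.80 for Timp3 among vessel genes, and 0.83 for Nfkbia, 0.63 for Csf1r and 0.93 for Aldh1l1. Metabolic genes differed by 0.88 for Atp5g1, 0.67 for Pgk1, −0.54 for Asns, 1.73 for Fmo2 and 2.65 for Acss3. Genes of neurons and myelin differed by −0.79 for Snap25, −0.95 for Dpysl2, −1.11 for Ipcef1 and −0.68 for Ugt8a. The others were Best3 (3.76), Sntb1 (2.58), Ccdc187 (2.49), Pou2f3 (−2.13), Samd15 (−1.34), Nkapl (−1.25), Lemd1 (−1.22), Lrch2 (−1.13), Morc2b (−0.94), Trpc6 (−0.94) and Mcts2 (−0.94).

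A single library stood apart from the other 3 of its group in 18 of 346 groups of 4 tested, where chance gives about 1 in 20. Nic-free 1 did so for Gbp11 (1.36 CPM, others 1.47 to 1.49), Prrg4 (0.886, others 0.238 to 0.267), Fzd4 (10.8, others 4.07 to 4.99), Angptl4 (1.98, others 3.99 to 4.03) and Pgam2 (1.98, others 2.8 to 2.92), and Nic-free 4 for Timp3 (199, others 248 to 256). Room-air 3 did so for Tmem252 (43.8, others 11 to 13.5), Icam1 (24.4, others 11.1 to 12.9), Nqo1 (16.7, others 12.5 to 13) and Slc28a3 (6.11, others 4.15 to 4.27), and Room-air 2 for Klf6 (48.4, others 64.4 to 66.4). Smoke 4 did so for Slc7a5 (187, others 135 to 140) and Ciart (30, others 18.8 to 19.6), and smoke 3 for Lrp5 (38.4, others 26.4 to 28.3). In the air set it was air 1 for Nfkbia (52.1, others 35.8 to 38.2), air 2 for Per1 (89.1, others 62.5 to 65.4) and air 4 for Per2 (78.3, others 58.5 to 60.4) and Asns (38.7, others 47.8 to 49.2). Outside the gene counts, reads assigned to no feature made up 42.1% in the nicotine-free group, above 30.7% in its control.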

How the results depend on the processing

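The GC and length correction, the endothelial and choroid covariates and the omission of Nic 1 with Nic 2, which leaves 1 nicotine library assumed to vary like the other groups, were chosen after the data were seen. Calls depended on which air set served as control, on marker lists as covariates and on single libraries of the smaller comparisons, and no scaling moved the median of all genes by over 0.1. DESeq2 kept 3649 of 3753, 653 of 670, 4154 of 4273, 242 of 244, 3695 of 3761 and 900 of 925 calls, in the order of the report. Of the genes named, 1 of 42 called in nicotine-free against room air kept its call in every alternative (Dbp), 0 of 34 in nicotine against room air, 3 of 48 in nicotine against nicotine-free, 0 of 43 in smoke against air, 8 of 10 between the air sets and 0 of 10 in smoke minus nicotine. Unless a construction is given, the cause was not tested. Where a covariate or the choice of fit lowered a count, 72.4% of the variance of neuron markers (nicotine-free), 80.4% of choroid (nicotine) and 60.8% of endothelial markers (smoke) lay between the groups, and omissions leave fewer libraries.

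Nicotine-free against room air had 3753 genes past the threshold, and 8 with neuron markers as a covariate, 121 with choroid markers, 699 with the other air set as control and 707 with both air sets. Leaving out a library gave 2186 (Nic-free 2) to 3534 (Nic-free 1), with 2346 without Nic-free 4. Nicotine against room air had 670, and 1037 with 1 surrogate variable, 2570 with the endothelial and 0 with the choroid covariate (2090 unadjusted), 1629 with DESeq2, 348 with all libraries in 1 fit, 4961 with the other air set, 1080 with both and 3 without Nic 1 and Nic 2. Omissions gave 0 (Room-air 2, 3581 unadjusted, and Nic 1, 2424 unadjusted) to 2956 (Nic 3), with 111, 358 and 324 without Room-air 1, 3 and 4 and 422 without Nic 2. Nicotine against nicotine-free had 4273, and 7 with the neuron covariate and 1511 without Nic 1 and Nic 2, with omissions from 2401 (Nic 1) to 4679 (Nic 3).

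Smoke against air had 244, and 466 with no filter, 126 without robust estimation, 5 with replicate number as a block, 770 with 1 surrogate variable, 0 with the endothelial (1240 unadjusted) and 752 with the choroid covariate, 42 with the GC and length trend removed, 904 with DESeq2, 519 with all libraries in 1 fit, 1027 with the other air set and 53 with both. Omissions gave 1 (smoke 1) to 192 (air 1), with 5, 3 and 17 without air 2, 3 and 4 and 62, 133 and 11 without smoke 2, 3 and 4. The air sets differed in 3761 genes, and in 1230 with the neuron, 765 with the endothelial and 2133 with the choroid covariate, with omissions from 2415 (air 3) to 3496 (air 1) and 2459 without air 2. Smoke minus nicotine had 925, and 611 with the block, 596 with the endothelial and 246 with the choroid covariate, 361 with the GC and length trend removed, 1761 with DESeq2 and 0 without Nic 1 and Nic 2 (1583 unadjusted). Omissions gave 13 (Nic 1) to 2476 (Nic 3), with 53 without Nic 2, 460 and 238 without Room-air 1 and 2, 207, 383 and 588 without air 1, 2 and 3 and 469 without smoke 2. With the other air set as control 3 of 15 lists kept their camera call in nicotine-free, 8 of 11 in nicotine and 3 of 20 in smoke, and 6, 1 and 3 were called the other way. With the endothelial covariate 10 of 15 did in nicotine-free, 5 of 11 in nicotine, 8 of 16 in nicotine against nicotine-free (4 changed direction), 6 of 20 in smoke (3 called the other way), 9 of 16 between the air sets (1 called the other way) and 5 of 10 in smoke minus nicotine. Without Nic 3, 4 of 11 did in nicotine, and without Nic 2 or without smoke 4, 5 of 10 did in smoke minus nicotine. With the neuron covariate 8 of 15 lists kept their call in nicotine-free, 11 of 11 in nicotine and 10 of 16 in nicotine against nicotine-free. It was 11 of 20 in smoke, 12 of 16 between the air sets and 7 of 10 in smoke minus nicotine. Of 88 gene lists called by camera, 1 was called with an estimated correlation and 34 with fry, and the correlation of 0.725 between nicotine-free and the air set averaged 0.511 with separate pairs of controls.

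With the other air set as control, log2 fold changes of nicotine-free took the opposite sign for Gbp11 (−0.12), Ido1 (−0.11), Best3 (0.28), Map3k6 (0.10), Fzd4 (0.35), Cdkn1a (0.04), Ocln (0.21), Ctnnd1 (0.06), Slc2a1 (0.42), Lrp6 (0.16), Tsc22d3 (0.18), Lamb1 (0.03), Timp3 (0.26), Ndufb9 (−0.12), Rps19 (−0.38), Rpl38 (−0.65), Itm2a (0.31), Foxj1 (0), Mfsd2a (0.63) and Cyp1b1 (0.15). Those of nicotine did so for Best3 (0.80), Arntl (−0.04) and Cyp1b1 (0.94), and those of smoke for Zfp366 (−0.81), Gch1 (−0.05), Vsnl1 (0.18), Pcp4 (0.27), Dpysl2 (0.17), Slc7a5 (−0.58), Mfsd2a (−0.31), Lrp5 (−0.69), Nfkbia (−0.82), Per1 (−0.11), Klf4 (−0.43), Timp3 (−0.60), Abcb1a (−0.22), Notch3 (−0.11), Snap25 (0.03), Smtn (−0.35) and Slc2a1 (−0.86). Genes that passed with neither control also changed sign, in nicotine Vcam1 (0.37) and Hmox1 (0.27), and in smoke Ocln (−0.54), Cldn5 (−0.01), Vcam1 (−0.20), Cyp1b1 (−0.81) and Hmox1 (−0.11). In nicotine-free, genes that had not passed changed sign in some alternative too: Nqo1 (up to 0.27), Icam1 (up to 0.64), Hmox1 (down to −0.10) and Cldn5 (down to −0.18). With both air sets as control the sign changed for Rpl38 in nicotine-free (−0.10) and for Zfp366 (−0.18), Slc7a5 (−0.02), Lrp5 (−0.15), Nfkbia (−0.27), Timp3 (−0.13) and Slc2a1 (−0.29) in smoke, and among genes that did not pass for Mfsd2a in nicotine-free (0.03), Vcam1 (0.02) and Cyp1b1 (0.34) in nicotine and Ocln (−0.09) and Cyp1b1 (−0.43) in smoke. With the endothelial covariate Cldn5 was lower in nicotine against nicotine-free (−0.72) and higher in nicotine-free against room air (0.72). With the other air set as control Ocln (1.27), Slc2a1 (1.56), Mfsd2a (1.27), Cldn5 (0.82) and Tjp1 (0.55), which had not passed in nicotine against room air, did.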

Other observations

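All genes in this part were chosen after their values were seen. The clock list had the smallest spread within groups of all 35 lists, with a largest SD of 0.05 (mean log2 CPM) against 0.09 for the next, hypoxia-induced genes. It averaged 5.90 ± 0.03 in the Room-air set, 5.94 ± 0.05 in the nicotine-free, 5.98 ± 0.03 in the nicotine, 5.80 ± 0.02 in the air and 6.13 ± 0.05 in the smoke group (SD, n = 3 to 4), and smoke and air did not overlap (difference 0.33, exact two-sided permutation p 0.0286, adjusted 0.0715 over 5 comparisons). The air sets did not overlap either (difference −0.1, with the same exact and adjusted p). Its members did not follow 1 order of the groups: Dbp was at 75.4, 134, 80, 82 and 170 CPM in these groups in turn, Per1 at 147, 109, 144, 71.7 and 136, and Arntl at 43.6, 34.7, 52.8, 54.4 and 37.7. Dbp was thus highest and Arntl lowest in the nicotine-free and smoke groups, while Per1 was lowest in the air set.

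The 4 glucocorticoid-induced genes given here had higher means in the Room-air and nicotine groups than in the other 3, while Mt1, of the same list, was lower in nicotine than in nicotine-free (log2 −1.14). Cdkn1a was at 99.2 and 77.3 CPM in the former and at 23, 22.3 and 16.8 in the nicotine-free, air and smoke groups. Sgk1, a kinase that regulates ion transport, was at 188 and 111 against 56.2, 55.4 and 68.2, Tsc22d3 at 161 and 136 against 67.3, 59.5 and 81.8, and Fkbp5, a chaperone of the glucocorticoid receptor, at 40.9 and 27.1 against 20.3, 17.6 and 19. Libraries overlapped for Sgk1, with Nic 1 at 72.9 and smoke 3 at 115, and for Fkbp5, with Nic 1 at 19.5 and Nic-free 2 at 24.2. The Room-air and nicotine libraries are also those with the greatest depth.

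Hormone transcripts of the pituitary and hypothalamus were seen in some libraries. Gh was at 3.32 to 6.78 CPM in the smoke libraries and 4.93 in Nic-free 4, with 15 reads over the Room-air set and none in the nicotine group. Prl, the gene of prolactin, was at most 0.6 CPM (Nic-free 4) and at 0.16 to 0.382 in smoke, and Pomc, the precursor of corticotropin, at 4.86 to 7.85 in smoke, 1.91 to 6.01 in the Room-air set, 2.08 to 5.14 in nicotine-free, 1.59 to 3.41 in nicotine and 2.28 to 3.36 in the air set. Room-air 1 held Oxt at 21.4, Avp at 35 and Hcrt at 5.45 CPM, and air 2 held Pmch at 33 and Hcrt at 6.22. Ttr, the transthyretin gene of the choroid plexus, ran from 834 CPM in Nic-free 4 to 24700 in smoke 3. Gm42418, a transcript that overlaps ribosomal RNA sequence, ran from 591 in smoke 1 to 9400 in air 2, and Kif5a, a kinesin of neurons, from 1570 in Nic 1 to 13500 in smoke 2. Gm42418 did not overlap between smoke (591 to 1620) and air (1960 to 9400), nor between nicotine-free (5310 to 5720) and the Room-air set (2350 to 4330). In nicotine it was at 1790 to 4290, which overlapped the Room-air set.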
